A study of Homo sapiens with 4 samples.

How the data were processed

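RNA from 2 subclones of the DU145 prostate cancer line was labelled with biotin and hybridised to Affymetrix gene arrays, 2 arrays per clone, per the labels' protocols. Samples were grouped by their titles, which name the clone and a replicate number. The deposited values were log2 signals per probe set, 33297 on each array, and were used as deposited by the authors. The log2 scale was read from the values, which ran from 2.38 to 13.72 with nearly equal quantiles on all arrays, so that some normalization between arrays had been applied. Partek 6.6 and MAS5 are named in the submitters' processing notes with no role. The method that summarised probes, the background correction and any centring are not given in the sources used here, so an absolute level cannot be compared between probe sets. No detection calls or spot flags were used, because the table held signals only.

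Gene names came from the platform's annotation table. It gave exactly 1 gene symbol for 19460 probe sets, several for 1754, and did not list 12083, which are unnamed here. The Entrez identifiers of 19429 single-symbol probe sets were found in the RefSeq gene table of assembly GRCh38.p14, which was used only for names and for the order of genes along chromosomes. A gene was represented by its single-symbol probe set with the highest mean, which gave 18417 genes, 769 of them with more than 1 probe set. Among 26 called genes with several tested probe sets, 1 had probe sets of opposite sign and 0 were called in both directions by limma. Control probe sets, which the plan left out, carry no distinguishing names in the table. Among 3815 tested probe sets that the annotation did not list, where any controls would be, 161 were called.

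Values under the 20th percentile of all values (4.12) were set to it, and probe sets at or above the median of all values (6.11) on at least 2 arrays were tested. A group with both values under that median is called dim. EL was compared with ML in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a trend, on 2 residual degrees of freedom before moderation, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Intervals are 95% intervals of the moderated fit. Differences are log2 differences of means, EL minus ML, and fold changes are their powers of 2. A fold change is a lower bound where a value was set to the floor. An exact test of 2 arrays against 2 cannot go below the threshold, so only limma's adjusted p is given. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables, and matplotlib 3.10.9 drew the figures.

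The lists of genes, the rule for genes named in the text, the tests and most alternatives were fixed before the data were examined. Named genes were 20 chosen in advance, the 12 with the largest positive and the 12 with the largest negative log2 difference among called genes, and in each list up to 4 called members with the largest differences plus up to 2 in the opposite direction. This gave 109 genes; 2 of the 20 had no probe set of their own in the annotation and were not analysed here, and other genes named outside the rule were chosen after their values were seen (ATF4, SLC2A14, the neighbours of PCK2, genes at the ends of chromosomal runs and single genes in the closing observations). Of 30 lists, 27 had at least 5 tested members and were tested with limma's camera with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Of these, 5 passed, and 0 passed with an estimated correlation (smallest unadjusted p in camera 0.0653, 0 lists under 0.05 unadjusted) or in fry for a shift in a single direction (6 lists under 0.05 unadjusted), while 23 passed fry for changes in either direction. Fry does not compare a list with other genes. With an estimated correlation camera works on the 2 residual degrees of freedom, so it had little power to pass any list. The serine and one-carbon list had an estimated correlation of -0.052, under the preset 0.01, yet its unadjusted camera p rose from 0.000417 to 0.0653. A failure there therefore does not decide against a list. The other lists that passed had estimated correlations above the preset. These were 0.039 for glycolysis, 0.16 for ATF4 targets, 0.347 for interferon-stimulated genes and 0.448 for hypoxia. Their camera p-values with the preset correlation may thus be too small. Members past the threshold were counted over all genes tested and adjusted over the list alone, and where the second count is not given it equalled the first.

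The fit was tested on simulated data: in 5 simulated tables of 17006 probe sets, the share of changed probe sets recovered was 0% at a log2 change of 0.5, 18.4% at 1, 52.8% at 1.5 and 70.4% at 2, and 0.3% of calls were false. In those tables differences under a log2 change of 1 were thus recovered rarely. They held 250 changed probe sets of each size over all 5 tables, far fewer per table than the 1201 called in the data. The adjusted threshold was therefore stricter there. Simulated noise was also independent between probe sets and arrays, without the replicate differences that both clones share in the data. Its spread was drawn from estimates on 2 residual degrees of freedom. For these reasons the shares do not carry over to the data. Of 559 higher and 642 lower calls in the data, only 147 and 206 differed at least 2-fold. Alternatives were quantile normalization, median centring, no floor, an offset of 32 on the linear scale, no filter, a stricter filter (70th percentile), eBayes without a trend and with robust estimation, a replicate block, each array left out in turn, the mean of a gene's probe sets, and a 2-fold minimum. Added after seeing the data were no filter with no floor, single-gene probe sets only, and subtraction of the median EL minus ML difference of up to 15 tested neighbours on each side. Leaving out an array leaves a clone with a single array and fewer residual degrees of freedom, so eBayes leans on the spread of other probe sets. Adjusted p-values of called genes could then be far smaller than with all arrays. Calls kept, lost or gained in those fits are therefore not on the scale of the main fit. For neighbouring genes, 11506 tested genes with a chromosomal position were put in order and running medians over 31 genes were taken within chromosomes. Runs named in the text are stretches of at least 10 genes whose running median was beyond 0.30 in size, the largest in the other splits of the arrays.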

Results

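Gene expression was compared between 2 subclones of DU145, an established human prostate cancer cell line. The labels describe the epithelial-like (EL) clone as more tumorigenic and richer in tumour initiating cells than the mesenchymal-like (ML) clone. Each clone was measured on 2 Affymetrix gene arrays, from untreated cells in serum-containing medium. The labels call the arrays of a clone biological replicates without saying whether they came from separate cultures, so the p-values below measure only the spread between these arrays, which may be technical. Each array gave a log2 signal for 33297 probe sets, with medians from 6.08 to 6.13. Across probe sets, which are not independent replicates, the correlation between replicates was 0.993 in ML and 0.996 in EL, and between arrays of different clones it ran from 0.988 to 0.989. The SD of the log2 difference between replicates was 0.27 in ML and 0.21 in EL, and between clones 0.34 to 0.36. The small number of arrays limits the precision of every value.

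The series asked which genes were expressed differently in the EL and ML clones, and several of those furthest below ML were dim in EL. Detection calls were not used, so a dim signal may be background, and a fold against it describes array signals and carries no order. NFIB, a transcription factor of the nuclear factor I family, averaged 9.60 ± 0.17 (SD, n = 2) in ML and was dim in EL, at least 44.1-fold lower (log2 difference -5.46, 95% interval -5.80 to -5.13, limma adjusted p = 1.24e-08). BCHE, which encodes butyrylcholinesterase, averaged 8.37 ± 0.14 in ML and lay under the floor on both EL arrays, at least 19.0-fold lower. The pseudogene NMRAL2P averaged 9.99 in ML and a dim 5.07 in EL (log2 difference -4.92). PAPPA, a metalloproteinase that cleaves insulin-like growth factor binding proteins, was also dim in EL (log2 difference -3.90). TXNIP, the thioredoxin-interacting protein that restrains glucose uptake, was 12.4-fold lower. It was uneven between EL arrays, 6.19 and 7.47, and its log2 difference of -3.63 was -2.99 without EL replicate 1 and -4.27 without EL replicate 2. The other genes among the 12 furthest below ML were CD24, PLPP4, SERPINA1, IFITM3, PIP4K2A, C3 and the cholesterol exporter ABCA1, with log2 differences from -3.33 to -2.73. Of these, PLPP4, IFITM3, PIP4K2A and ABCA1 were dim in EL. In the opposite direction, SLC2A3, the neuronal-type glucose transporter GLUT3, averaged 9.33 ± 0.28 in EL against a dim 5.27 ± 0.56 in ML, 16.7-fold higher (log2 difference 4.06, adjusted p = 3.39e-06). CRISPLD1, the axon guidance receptor gene ROBO1 and CSGALNACT1, an enzyme of chondroitin sulfate synthesis, averaged 9.16, 8.35 and 8.75 in EL and were dim in ML (5.90, 5.11 and 5.65). ABCC2, an organic anion exporter, was 8.34-fold higher. NTN4, RNF212, INA, PARM1, HAS2, TFAP2C and EPHX3 completed the 12 furthest above ML, with log2 differences from 2.62 to 2.44. Of these, INA, PARM1, HAS2 and EPHX3 were dim in ML. HAS2 lies in a run of 32 tested genes, from LRP12 to TYW2, with a median of 0.34. MAL2, in the same run, went the other way (-1.39). Probe sequences of CD24, SLC2A3 and IFITM3 may be shared with close copies elsewhere in the genome, so their values are uncertain in source. SLC2A14, the nearest relative of SLC2A3, was dim in both clones (5.13 in ML, 5.63 in EL).

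Of 17006 probe sets bright enough to test, 559 were higher and 642 lower in EL at a limma adjusted p under 0.05, 7.1% of those tested, and 147 and 206 of these differed at least 2-fold. Counted by gene, 441 of 11528 were higher and 513 lower. The values of the clones did not overlap for 47.4% of tested probe sets, against 33.3% by chance for 2 arrays against 2. Leaving out EL replicate 1 moved the lower count by over 1.5 times (415 higher and 370 lower), and leaving out EL replicate 2 the higher count (294 and 495). Both counts moved by over 1.5 times without ML replicate 1 (1030 and 1064) or ML replicate 2 (921 and 979). Of the 22 gene lists below that were tested and did not pass, 20 had a median that moved by over 1.5 times or turned sign without some array, 9 of them turning sign. Several of these medians lay near 0, where small changes meet this rule. For cell cycle genes the median was 0.06, and 0.11 without EL replicate 1. With no filter on dim probe sets, 1 probe set was higher and 0 were lower by limma, although 2187 and 2028 had an unadjusted p under 0.05. With neither filter nor floor, 196 were higher and 287 lower.

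PCK2, the mitochondrial phosphoenolpyruvate carboxykinase named in the series title, was higher in the EL clone. Its probe set (7973530) averaged 8.62 ± 0.33 (SD, n = 2) in EL and 7.08 ± 0.10 in ML, 2.90-fold higher (log2 difference 1.53, 95% interval 1.12 to 1.95, adjusted p = 0.000606), and both EL values lay above both ML values. PCK1, the cytosolic form of the enzyme, was dim in both clones, at 4.63 in ML and 4.71 in EL, and was not tested. Among the 5 tested genes of gluconeogenesis, PCK2 was the only gene past the threshold over all genes tested (2 genes adjusted over the list alone), and the list was not past the threshold (median log2 difference 0.03, camera adjusted p = 0.261). Without EL replicate 2 it was past it (median 0.17, adjusted p = 0.04), and without the other arrays its median ran from -0.12 to 0.18. In limma the adjusted p of PCK2 was 0.24 with no filter on dim probe sets. It was 0.0193 with neither filter nor floor, an alternative chosen after the data were seen. Genes beside PCK2 on its chromosome were also higher in EL: the 20 nearest tested neighbours, 10 on each side, had a median log2 difference of 0.41, and 19 of them were above 0. SLC22A17 was higher by 1.51, NGDN by 1.21, EMC9 by 0.82 and DCAF11 by 0.82, each with an adjusted p under 0.05, although the call of DCAF11 was lost without EL replicate 1 (0.0715) or ML replicate 2 (0.0539). With the median of 15 neighbours on each side subtracted, a step chosen after the data were seen, PCK2 was higher by 1.08 (adjusted p = 0.00031).

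**Figure D1:**
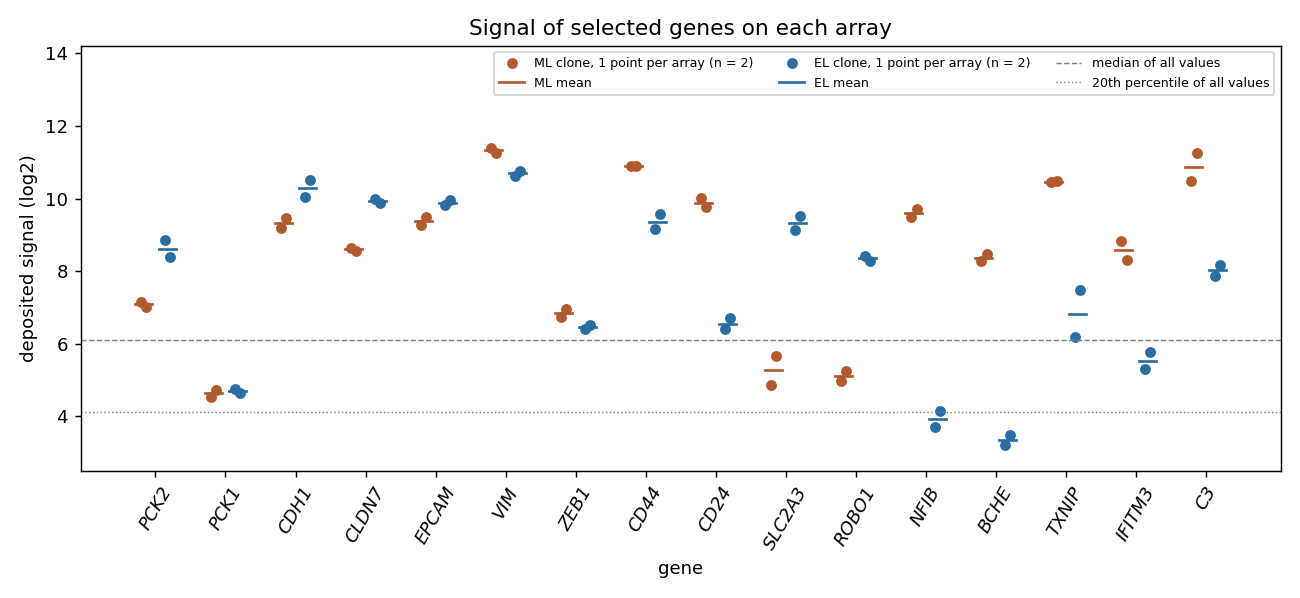
Deposited log2 signal (vertical axis) of 16 genes on each array; points are arrays (2 per clone), short lines are means of the plotted values, the dashed line is the median of all values (6.11) and the dotted line their 20th percentile (4.12). PCK2, CDH1, CLDN7, SLC2A3 and ROBO1 lie higher in EL, and VIM, CD44, CD24, NFIB, BCHE, TXNIP, IFITM3 and C3 lie higher in ML; the EPCAM and ZEB1 differences were not past the threshold, and PCK1 is dim throughout.

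**Figure D2:**
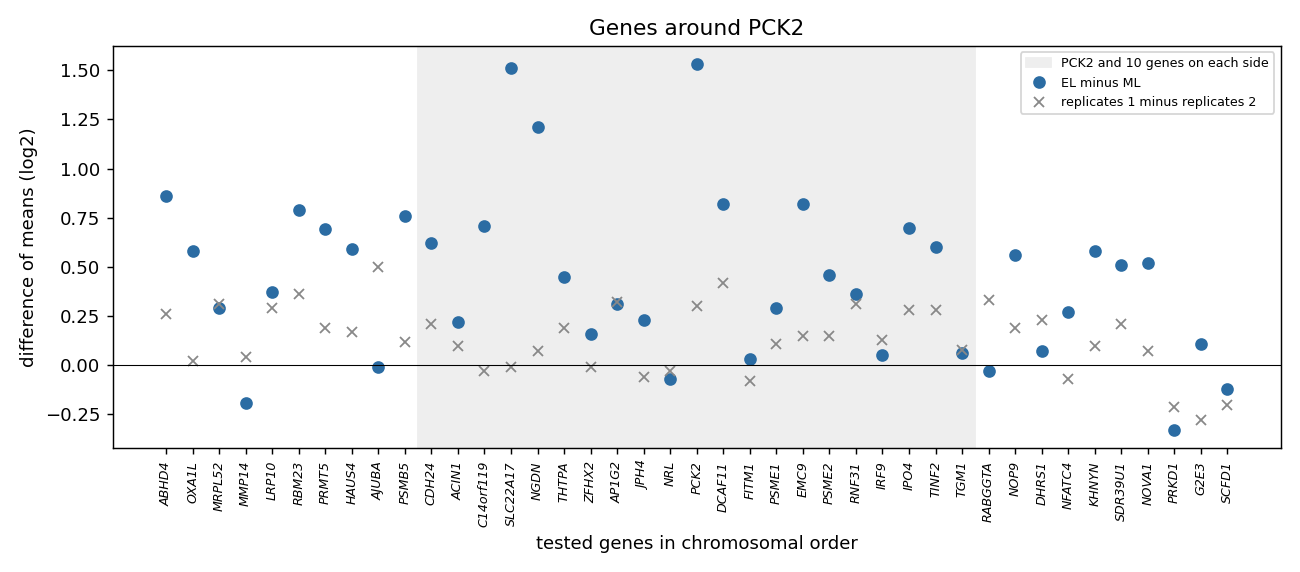
Log2 difference of means (vertical axis) for PCK2 and the 20 tested genes on each side of it, in chromosomal order; circles are EL minus ML, crosses are replicates 1 minus replicates 2 over both clones, and grey shading marks the 10 genes on each side. In the shaded part the neighbours have a median of 0.41 for EL minus ML and 0.12 for the replicates.

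Of 33 tested epithelial junction and splicing genes, 2 were higher and 3 lower in the EL clone, or 3 and 3 adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.37). CDH1, which encodes E-cadherin, averaged 10.28 ± 0.32 in EL and 9.31 ± 0.19 in ML, 1.95-fold higher (log2 difference 0.96, adjusted p = 0.0132), and the tight junction gene CLDN7 was 2.54-fold higher (adjusted p = 0.00069). MAL2, an apical trafficking protein, and CLDN4, another claudin, were lower in EL by 1.39 and 1.21 on the log2 scale (log2 differences -1.39 and -1.21). MAL2 went against its chromosomal run, which had a median of 0.34. EPCAM differed by 0.51, which was not past the threshold (adjusted p = 0.109), although its call was gained without ML replicate 2 (0.0394). The CDH1 call was lost without EL replicate 2 (log2 difference 0.73, adjusted p = 0.154).

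Of 22 tested mesenchymal genes, 3 were higher and 5 lower in the EL clone (3 and 6 adjusted over the list alone), and the median of -0.21 was not past the threshold (camera adjusted p = 0.177; 0.0326 without EL replicate 2 and 0.0206 with a stricter filter). TNC, which encodes the matrix protein tenascin C, was 6.18-fold lower in EL (log2 difference -2.63, adjusted p = 7.46e-06), LOX, a collagen crosslinking oxidase, 3.90-fold lower and dim in EL, and VIM, the intermediate filament vimentin, 1.55-fold lower (11.33 ± 0.10 in ML, 10.70 ± 0.09 in EL, adjusted p = 0.0167). FSTL1, TGFB2 and FN1, which encodes fibronectin, were higher in EL by 1.12, 0.93 and 0.78, FN1 from a dim level in ML. The transcription factors ZEB1 and SNAI2 differed by -0.38 and -0.36, with adjusted p = 0.176 and 0.263, and CDH2, which encodes N-cadherin, was dim in both clones. VIM and ZEB1 lie, with PIP4K2A, in a chromosomal run of 38 tested genes from FAM171A1 to CUL2. Its other genes had a median of -0.59 beside VIM, so that the VIM difference was about that of its neighbours. With neighbourhood medians subtracted, the median of the mesenchymal list went from -0.21 to 0.02 (camera adjusted p = 0.464). Without EL replicate 1 the adjusted p of VIM was 0.109, and without EL replicate 2 that of TGFB2 was 0.163 and FN1 differed by 0.46 (adjusted p = 0.321). FN1 was also not past the threshold without a trend in eBayes (0.0569).

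The surface markers CD44 and CD24, both in the list of stem and tumour initiating cell markers, were lower in the EL clone. The list gives markers no direction, so a lower value does not by itself mean fewer such cells. CD44, the hyaluronan receptor, averaged 9.36 ± 0.28 in EL and 10.89 in ML, 2.90-fold lower (log2 difference -1.54, adjusted p = 0.000337), and CD24 was 10.1-fold lower (log2 difference -3.33). Bone morphogenetic protein gene BMP7 was 4.03-fold higher in EL from a dim level in ML (adjusted p = 8.3e-06), and ALDH1A3, an aldehyde dehydrogenase, KLF4 and MYC were higher by 0.78, 0.54 and 0.65. A second, dimmer probe set of ALDH1A3 differed by 0.42 and was not past the threshold (adjusted p = 0.121). Of 21 tested stem and tumour initiating cell markers, 5 were higher and 2 lower (5 and 3 adjusted over the list alone), with a median of -0.03 (camera adjusted p = 0.988). The integrin gene ITGA2, in a run of 24 tested genes from TMEM267 to PLK2 with a median of -0.43, and ITGA6 differed by -0.89 and -0.22 (adjusted p = 0.165 and 0.722), and PROM1, ALDH1A1, ABCG2 and SOX2 were dim in both clones and not tested. ITGA2 was past the threshold without EL replicate 2 (-1.34, adjusted p = 0.000224) or ML replicate 1 (-1.42, 2.09e-07), and differed by -0.44 without EL replicate 1 (0.584) and -0.35 without ML replicate 2 (0.372). ITGA6 was above 0 without EL replicate 1 (0.09) or ML replicate 2 (0.10). ITGA2 and ITGA6 were higher on replicate 2 than on replicate 1 in both clones. For ITGA2 the values were 9.53 and 10.6 in ML and 8.73 and 9.63 in EL. Leaving out 1 array unbalances this shared difference. Calls of KLF4 and MYC were lost without EL replicate 1 (adjusted p = 0.0927 and 0.396) or EL replicate 2 (0.336 and 0.16), and that of ALDH1A3 without EL replicate 2 (0.323). KLF4 also lost its call without a trend in eBayes (0.0634).

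The list of targets of ATF4, the transcription factor of the amino acid response, also holds ATF4 itself. Of its 31 tested members, 9 were higher in the EL clone, 1 was lower and 21 did not pass the threshold. The list's median was 0.42 (camera adjusted p = 2.97e-08, and adjusted p = 0.77 with an estimated correlation). ALDH1L2, a mitochondrial folate enzyme, was 3.06-fold higher in EL (7.38 ± 0.09 against a dim 5.77 ± 0.04, adjusted p = 5.02e-05), the cystine transporter gene SLC7A11 was 2.81-fold higher (adjusted p = 0.00728), and CHAC1, a glutathione-degrading enzyme, 2.76-fold (adjusted p = 0.0238). PCK2 was another of the 9, and the lower gene was that of the angiogenic factor VEGFA (log2 difference -0.82, adjusted p = 0.0101). Adjusted over the list alone, 17 were higher and 2 lower. CHAC1 was uneven between EL arrays, 9.90 and 8.53, and without EL replicate 1 it differed by 0.78 (adjusted p = 0.0806) and without EL replicate 2 by 2.15; robust estimation in eBayes ended its call too (0.15). ATF4 itself differed by 0.39 (adjusted p = 0.186). Of 12 tested serine and one-carbon genes, 2 were higher and 10 did not pass the threshold, with 5 higher adjusted over the list alone and 0 lower by limma either way. Their median was 0.32 (camera adjusted p = 0.00282, and adjusted p = 0.77 with an estimated correlation). The higher genes were ALDH1L2 and that of the mitochondrial folate enzyme MTHFD2 (log2 difference 0.69, adjusted p = 0.00898). ALDH1L2, PHGDH and PSAT1 are also in the ATF4 list, so these list shifts are not separate. ASNS, which encodes asparagine synthetase, was 2.08-fold higher and was the 1 gene past the threshold among 8 glutamine and transaminase genes (median 0.07, camera adjusted p = 0.432).

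Of 24 tested hypoxia response genes, 2 were higher and 9 lower in the EL clone (3 and 11 adjusted over the list alone). The median was -0.38 (camera adjusted p = 0.00282, and adjusted p = 0.77 with an estimated correlation), and the call was lost without EL replicate 1 (median -0.24, adjusted p = 0.31) or ML replicate 2 (-0.19, 0.357). Without EL replicate 1, 4 were lower. LOX was lower, as above, in a chromosomal run of 175 tested genes from MARVELD2 to CXXC5 with a median of -0.37. STC1, which encodes the hormone stanniocalcin 1, was 2.29-fold lower (log2 difference -1.19, adjusted p = 0.0129), and VEGFA was 1.76-fold lower. ANGPTL4, a lipoprotein lipase inhibitor, and ADM, which encodes the peptide adrenomedullin, were 3.48-fold and 2.60-fold higher (adjusted p = 0.00275 and 0.000703). SLC2A1 and PFKFB4 of the hypoxia list are also in the glycolysis list, so these lists overlap. Glycolysis and lactate export genes held the large gain of SLC2A3 beside lower SLC2A1, the widely expressed glucose transporter GLUT1 (log2 difference -0.71, adjusted p = 0.00898), ENO2 (-0.75) and PFKFB4 (-0.64). That was 1 higher and 3 lower of 21, with a median of -0.19 (camera adjusted p = 0.0242, and adjusted p = 0.77 with an estimated correlation). The list's call was lost on leaving out any array (adjusted p from 0.583 to 0.838) and with median centring (0.24). ENO2 and PFKFB4 lost their calls without EL replicate 1 (adjusted p = 0.303 and 0.209) or EL replicate 2 (0.0746 and 0.0677).

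**Figure D3:**
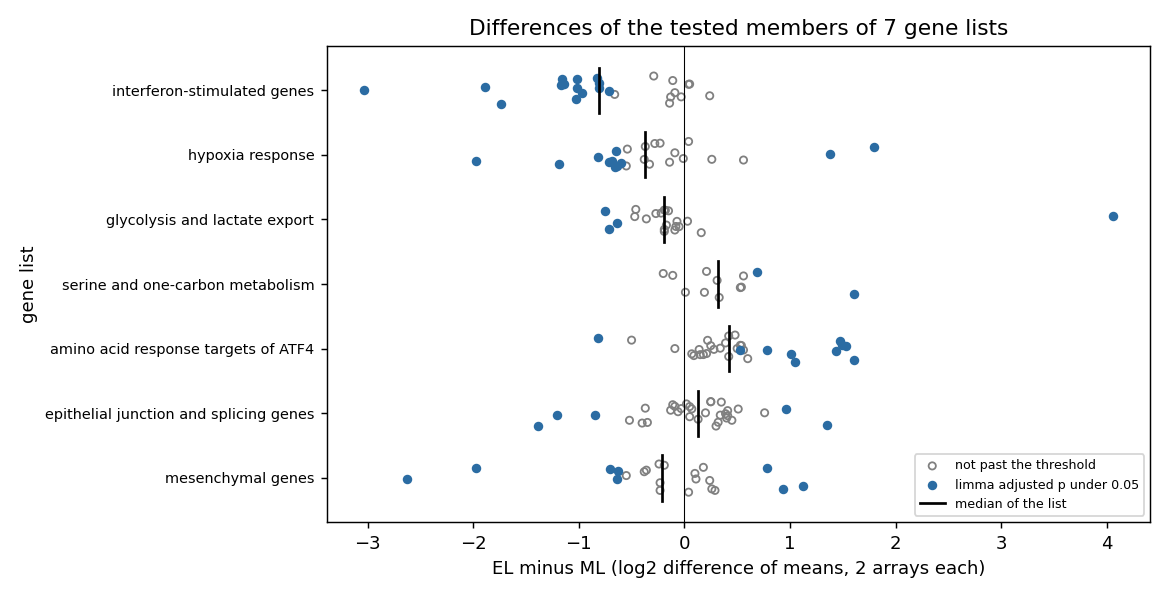
EL minus ML log2 differences (horizontal axis) of the tested members of 7 gene lists; filled points are genes with a limma adjusted p under 0.05, open points the rest, black lines the list medians. Medians run from -0.81 for interferon-stimulated genes to 0.42 for targets of ATF4.

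In mitochondrial and lipid metabolism, single genes but no list passed the threshold. SUCLG2, a subunit of succinyl-CoA ligase, was 2.55-fold lower in EL (log2 difference -1.35, adjusted p = 0.00158) and was the 1 of 15 tricarboxylic acid cycle genes past the threshold (median -0.10, camera adjusted p = 0.177). MPC1, a subunit of the mitochondrial pyruvate carrier, was dim in EL and lower by 0.63 (log2 difference -0.63, adjusted p = 0.0315), the 1 of 13 genes of pyruvate dehydrogenase and its kinases (median -0.08, 0.305), and NDUFS4 of complex I, in the same run as ITGA2 (median -0.43), differed by -0.74, the 1 of 38 respiratory chain and ATP synthase genes (median -0.06, 0.177; 0 genes adjusted over the list alone by limma). ACSL4, a long-chain acyl-CoA synthetase, and ELOVL6, a fatty acid elongase, differed by -1.14 and -0.82, and ACACB by 0.68, giving 1 higher and 2 lower of 18 in acetyl-CoA and fatty acid synthesis (median 0.03, camera adjusted p = 0.888). SQLE was the 1 of 17 cholesterol synthesis genes that was higher (0.85; list median -0.01, camera adjusted p = 0.922), and RPIA the 1 of 9 pentose phosphate genes (0.71; median 0.17, 0.177). Without EL replicate 1 the adjusted p was 0.155 for MPC1, 0.213 for NDUFS4, 0.378 for ELOVL6 and 0.0556 for ACACB. Without EL replicate 2 it was 0.0801 for NDUFS4, 0.102 for ACACB, 0.0933 for SQLE and 0.147 for RPIA, and without ML replicate 1 it was 0.0674 for MPC1 (0.0518 without a trend in eBayes).

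Of 24 tested interferon-stimulated genes, 14 were lower in the EL clone, 10 did not pass the threshold and 0 were higher in the limma fit (15 lower and 0 higher adjusted over the list alone). The median was -0.81 (camera adjusted p = 2.49e-12, and adjusted p = 0.77 with an estimated correlation). Without EL replicate 1, 8 were lower. IFITM3, which blocks virus entry, averaged 8.58 ± 0.37 in ML and a dim 5.54 ± 0.32 in EL, 8.18-fold lower (log2 difference -3.03, adjusted p = 8.72e-06). The antiviral GTPase gene MX2 was 3.71-fold lower, the guanylate-binding protein gene GBP2 3.34-fold, both to a dim level, and PARP14 2.25-fold. Of 15 tested antigen presentation genes, 2 were higher and 4 lower (3 and 4 adjusted over the list alone): the peptide-trimming enzymes ERAP2 and ERAP1 were 5.54-fold and 2.55-fold lower, and PSMB8 and NLRC5 were lower by 0.91 and 0.71 (log2 differences -0.91 and -0.71), NLRC5 to a dim level, while HLA-DMB and TAP1 were each higher by 0.65. A second probe set of HLA-DMB differed by 0.61 (adjusted p = 0.0586). ERAP1 and ERAP2 lie in the same run of 175 genes as LOX, with a median of -0.37. The antigen presentation list's median of 0.07 and its mean of -0.18 had opposite signs, and camera, whose direction was down, gave an adjusted p of 0.432. The calls of HLA-DMB and TAP1 were each lost without EL replicate 1 (adjusted p = 0.144 and 0.215), EL replicate 2 (0.311 and 0.269) or ML replicate 2 (0.116 and 0.0825). Without EL replicate 2 that of NLRC5 was lost (0.0853), and without ML replicate 1 PSMB8 differed by -0.59.

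Of 22 tested NF-kB targets and cytokines, 3 were higher and 4 lower in the EL clone (5 and 8 adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.177). The chemokine genes CCL20 and CCL5 were 3.64-fold and 2.33-fold higher in EL (adjusted p = 0.00246 and 0.00453), and LCN2, an iron-siderophore binding protein, and the cytokine gene IL6 were 3.33-fold and 2.84-fold lower (adjusted p = 0.0003 and 0.000209). The third higher gene, the inhibitor NFKBIA, differed by 0.42, and its call was lost without EL replicate 1 (adjusted p = 0.0641), without EL replicate 2 (0.414), with median centring (0.0704) and without a trend in eBayes (0.145).

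Genes of the matrix, adhesion and growth factor signalling gave no list past the threshold. Among TGF-beta and YAP targets, ANKRD1 was 3.09-fold lower, CCN2, THBS1 and the receptor kinase gene AXL were lower by 0.91, 0.71 and 0.70 (log2 differences -0.91, -0.71 and -0.70), and LTBP1 was 2.34-fold higher, for 4 higher and 4 lower of 26 (5 and 5 adjusted over the list alone; median 0.00, camera adjusted p = 0.922). The secreted protein gene DKK3 was 2.78-fold lower, and the Notch targets HEY2, dim in ML, and NRARP were higher by 0.83 and 0.82, for 2 higher and 1 lower of 26 Wnt and Notch genes (median 0.18, camera adjusted p = 0.177). ADAM8 was 3.49-fold lower and the inhibitor TIMP1 1.80-fold lower, while MMP15 and HPSE were higher by 0.75 and 0.67, for 2 higher and 3 lower of 20 matrix proteases and inhibitors (4 and 4 adjusted over the list alone; median 0.03, mean -0.05, camera adjusted p = 0.891 with direction down). Integrin genes ITGB4 and ITGB3 were 2.57-fold and 1.61-fold lower, the 2 of 16 integrins and laminins past the threshold. The list's median was -0.18 (camera adjusted p = 0.135). It was -0.30 without EL replicate 2 (0.0326), -0.01 without EL replicate 1 and 0.04 without ML replicate 2. PDLIM7 was the 1 of 25 cytoskeletal genes (log2 difference -0.90; median -0.13, camera adjusted p = 0.268). Without EL replicate 1 the adjusted p was 0.318 for THBS1, 0.11 for MMP15, 0.0681 for HPSE and 0.331 for ITGB3. Without EL replicate 2 it was 0.186 for CCN2, 0.0931 for THBS1, 0.125 for MMP15, 0.514 for HPSE and 0.164 for PDLIM7, and without ML replicate 2 it was 0.074 for THBS1.

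Glutathione and NRF2 target genes were led by ABCC2 and SLC7A11, which were higher in EL, whereas the aldo-keto reductase genes AKR1C2 and AKR1C3, near-identical relatives whose signals may mix, were 3.95-fold and 2.46-fold lower, both dim in EL. Of 21 tested members, 5 were higher and 2 lower (6 and 3 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.124; 0.04 without EL replicate 2 and 6.37e-05 with a stricter filter). Of 37 tested cell cycle genes, 1, E2F1, was higher (log2 difference 0.76, adjusted p = 0.0249; 0.222 without EL replicate 1), and the median was 0.06 (camera adjusted p = 0.261).

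Among markers of prostate cell states, single genes but no list passed the threshold. In the basal list ITGB4 was lower, as above, and CDH3, which encodes P-cadherin, was 2.56-fold higher in EL (adjusted p = 0.00101), for 1 higher and 1 lower of 10 (2 and 3 adjusted over the list alone; median -0.02, camera adjusted p = 0.922). NDRG1 was the 1 of 9 luminal and androgen response markers past the threshold (log2 difference -0.69, adjusted p = 0.0479; median 0.05, camera adjusted p = 0.922). Of 4 tested neuroendocrine markers, too few for camera, DLL3 was higher by 0.56 and ENO2 lower. The calls of NDRG1 and DLL3 were lost without EL replicate 1 (adjusted p = 0.356 and 0.344) or ML replicate 2 (0.0795 and 0.0597), and without a trend in eBayes (0.0683 and 0.0705); that of DLL3 was also lost with quantile normalization (0.0502). Markers of other cells were mostly too dim to test. The filter kept 1 of 13 stromal fibroblast markers, which was not past the threshold, and 3 of 16 markers of leukocytes, endothelium and red cells, of which CD68, a lysosomal protein also made by tumour cells, was lower by 0.82 (log2 difference -0.82, adjusted p = 0.0117; 0.0935 without EL replicate 1).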

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

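Alternatives without a filter and floor, with single-gene probe sets and with neighbourhood medians subtracted were chosen after the data were seen. Counts of probe sets higher and lower in EL stayed within 1.5 times of 559 and 642 under quantile normalization, median centring, no floor, the linear offset, eBayes without a trend or with robust estimation, gene means and single-gene probe sets. They were 306 and 379 with a stricter filter, which tested 10363 probe sets, 671 of whose 685 calls were also called at first. They were 147 and 206 with a 2-fold minimum, 196 and 287 with no filter and no floor, and 1 and 0 with no filter but the floor kept. In that last limma fit 2187 and 2028 probe sets had an unadjusted p under 0.05, and the floor made 5859 of 33297 probe sets constant. The unfiltered fits with and without the floor differ only in it, so the fall from 196 and 287 calls to 1 and 0 came with the floor. How constant probe sets led to this was not tested. Leaving out an array gave 294 to 1030 higher and 370 to 1064 lower, with the lone array of a clone assumed to vary like the other clone's.

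PCK2 stayed past the threshold in all alternatives but no filter (difference 1.53, adjusted p = 0.24), with differences of 1.30 to 1.77 when an array was left out, 1.34 with the linear offset and 1.08 with neighbourhood medians subtracted. Of the 96 called genes named by the rule, 66 kept their call whichever array was left out and 30 lost it at least once. Fits with an array left out lean on spread pooled over probe sets, so a call kept there is weak evidence of stability. Besides PCK2, calls or their absence changed for 95 of 100 tested named genes with no filter, 47 with no filter and no floor, 6 without a trend, 2 with the block and 1 each with robust estimation, median centring and quantile normalization. ITGA6, not called, turned from -0.22 to 0.09 without EL replicate 1 and 0.10 without ML replicate 2, in a range of -0.55 to 0.10. It was higher on replicate 2 than on replicate 1 in both clones (9.59 and 10.24 in ML, 9.38 and 10 in EL). Leaving out 1 array unbalances this shared difference. Of 5 list calls, 0 remained in camera with an estimated correlation (0 lists unadjusted) and 0 in fry (6 unadjusted), and leaving out an array gave 3 to 8 lists. Glycolysis also lost its call without a trend (0.0508) and with neighbourhood medians subtracted (0.0771). Camera with an estimated correlation had little power on 2 residual degrees of freedom, so losses there do not decide against a list. For all list calls but that of serine and one-carbon genes, however, the estimated correlation was above the preset 0.01. Low signals limit the tests, since the 16291 probe sets under the filter were not tested.

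The 2 replicate numbers are shared by the clones, but the labels tie them to no batch. The differences of replicate 1 and replicate 2 correlated between clones across probe sets (r = 0.38). With a replicate block 1549 probe sets were higher and 1627 lower, including 1196 of the first 1201, PCK2 differed by 1.53 (adjusted p = 3.62e-07), 6 lists passed, and glycolysis did not (0.295). Calls gained with the block were those of EPCAM (0.00234) and ITGA2 (1.62e-05) among named genes, and of mesenchymal genes (0.0207) and glutathione and NRF2 targets (0.00425) among lists.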

Other observations

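Genes in the first paragraph were picked singly after their values were seen and stand for no group, and the tests that follow were also chosen after the results were seen, except that on gene families. Among genes lower in the EL clone, SERPINA1, which encodes the protease inhibitor alpha-1-antitrypsin, averaged 10.51 in ML and 7.42 in EL (8.52-fold lower), and C3, the central complement component, was 7.20-fold lower (log2 difference -2.85, adjusted p = 3.83e-05). The complement genes CFB, C1S and C1R were 4.77-fold, 3.66-fold and 1.78-fold lower (adjusted p = 0.000379, 3.48e-05 and 0.0131), and BMPER, which encodes an extracellular protein that binds bone morphogenetic proteins, 4.30-fold (log2 difference -2.10, adjusted p = 0.00022). Among genes higher in EL, BMP6 was 4.69-fold higher and BMP8A 1.97-fold, both from a dim level in ML, whereas BMP2 was dim in both clones (5.67 in ML, 5.69 in EL) and was not tested. The retinol-binding protein gene RBP7 was 4.62-fold higher, the motor protein gene KIF5C 4.09-fold and SYT11 3.53-fold, all dim in ML, the adhesion molecule gene CNTN1 3.40-fold and the retinol dehydrogenase gene RDH10 2.23-fold (adjusted p = 3.83e-05, 4.2e-05, 0.000184, 9.8e-05 and 0.00255).

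Over 41 tested histone cluster genes, also chosen after their values were seen, the median of replicate 1 minus replicate 2 was 0.33 in ML and 0.34 in EL. Of these genes, 35 were higher in replicate 1 in both clones. In a limma fit of replicates 1 against replicates 2, 0 probe sets of any kind passed the threshold (936 with an unadjusted p under 0.05). That fit held no term for the clone, so clone differences counted as spread, and its 0 does not show that replicates were alike. A median shows only a common shift, since opposite differences cancel. That shift was smaller between clones than between replicates over the histone cluster genes, chosen after their values were seen. Their median of EL minus ML was -0.06, with H4C13 and H3C11 higher by 2.15 and 1.03 and H4C8 lower (log2 difference -0.95, and -0.82 without EL replicate 2, where its call was lost).

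Neighbouring genes differed together between the clones. Running medians over 31 tested genes in chromosomal order reached -0.65 and 0.49 for EL minus ML. They were at most 0.30 in size when replicates 1 were set against replicates 2 and 0.13 in the remaining split. The correlation of adjacent genes was 0.23 for EL minus ML, 0.29 for replicates 1 against replicates 2 and 0.07 for the remaining split. Neighbours thus also moved together between replicates, with smaller running medians. Running medians lay beyond 0.30 in 17 segments of at least 10 genes, 12 lower and 5 higher in EL. The segment from FAM171A1 to CUL2 held 38 tested genes, VIM and ZEB1 among them, with a median of -0.60, that from MARVELD2 to CXXC5 175 genes at -0.37, and that from NDRG3 to MYBL2 33 genes at 0.41. Against regional structure common to replicates as the whole cause, the largest running median was still 0.60 in size after the profiles of both other splits were removed, and against gene families that share probe sequence it was 0.62 with 1 gene kept per name stem. Both values concern the single largest running median, so they bear on that stretch and not on the other segments. Copy number of these segments that differs between the clones is a candidate explanation with no test here, since DNA was not measured, and it stays open, as does regional regulation. In the segments 90.9% of genes moved the segment's way, but choosing segments by their running median fixes a high share, so this bears on neither.

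PCK2 lies in a segment higher in EL, from PRMT5 to IRF9 (22 genes, median 0.46), and 0.4% of windows of 20 neighbours along the chromosomes had a median as high as its own. A shift of the neighbourhood may be part of the PCK2 difference. As the whole cause it cannot be told apart from a change of PCK2 itself. PCK2 (1.53) lay above the upper quartile of its neighbours (0.70) and narrowly above the highest, SLC22A17 (1.51). With neighbourhood medians subtracted, its difference was still 1.08. Yet 2 of the 20, SLC22A17 and NGDN, reached the lower bound of the PCK2 interval (1.12). A higher level of amino acid response genes is the biological candidate. The 30 other tested members of the ATF4 list, ATF4 among them, had a median of 0.33 after neighbourhood subtraction. Their shift had a camera p of 4.82e-09 with the preset correlation and 0.1 with an estimated correlation. The second test had little power on 2 residual degrees of freedom and cannot decide, so this candidate stays open too.

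Shifts of the gene lists were set against the same segments. With neighbourhood medians subtracted, the median was -0.84 for interferon-stimulated genes, 0.37 for ATF4 targets, 0.31 for serine and one-carbon genes and -0.37 for hypoxia genes, each still past the camera threshold, which argues against segments as the source of these 4 shifts. The ATF4 list shares members with the serine and hypoxia lists, so these are not 4 separate shifts. For glycolysis the median moved from -0.19 to -0.18 and the adjusted p from 0.0242 to 0.0771, so that the call ended with little change in size, and the question stays open. All of these calls rest on the preset correlation, and before subtraction each list had a camera adjusted p = 0.77 with an estimated correlation. That test had little power on 2 residual degrees of freedom and does not decide between them.

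The 4 arrays allow 3 splits into pairs, too few for a share under 0.05. The split by clone gave 1201 probe sets past the threshold and was the only 1 of the 3 with any, the highest of the others giving 0 by limma (936 probe sets with an unadjusted p under 0.05 for replicates 1 against replicates 2, and 96 for the remaining split). Each of the other splits mixes the clones within its groups, so clone differences count as spread there and lower its count. The contrast of 1201 with 0 was thus in part set in advance.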
